A study of Danio rerio with 56 samples.

How the data were processed

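Single live cells of 7 zebrafish had been sorted into 384-well plates, and for each cell either edited GFP or GFP together with transcripts had been sequenced, per the labels. The deposited tables were used as they were given, and reads were not processed again. The transcript tables held an estimated count of transcripts per gene and cell, made by the authors from counts of unique molecular identifiers with a correction for identifiers drawn more than once. The correction was found in the values: with 4096 possible identifiers, every value inverted to a whole number of identifiers within a tolerance of 0.0001. The clone tables held, for each cell, the percent of GFP carrying each edit, computed by the authors, and per the file headers the edits were written as alignment operations over 720 bases. Clone numbers came from the same tables, and where 2 numbers were present the one read as covering the whole fish was used. The file headers do not define these numbers, and the reading was inferred from the column names and from how the numbers spread over organs. The submitters' processing notes named genome build Zv9, and the aligner, the counting tool, the annotation and the method of clone calling are not given in the sources used here. Gene symbols came from the tables, then from a list pairing gene identifiers with symbols, and genes without a symbol kept their identifier. No gene coordinates of that build were used.

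Cells were taken from the authors' annotation, which also gave the cell classes. For the head the newer of both annotations was used. Wells without an annotated cell were left out, as were 435 cells in the fin annotation that belonged to other fish. Spike-in transcripts were left out of all sums. Doublets were not called, and no filter on cells was added to that of the authors. Cells were joined to samples by the organ and the fish in their names.

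Transcripts were summed over the cells of each library and rounded to whole numbers, because cells of 1 fish are not replicates. For brain and midbrain, and for the eye of R1, the left and right libraries of a fish were summed first. The eye of R3 was the right eye alone, and the brain sum held forebrain and midbrain in both fish and the hindbrain in R1 only. Sums were compared between groups of 2 fish with the quasi-likelihood test of edgeR 4.0.16 with TMM factors and filterByExpr, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Both groups of each comparison came from the same fish. Fish as a replicate block was run as an alternative, because the replicate numbers were those of the animals. Within-fish correlation of the residuals was 0.0270 for fin, 0.217 for eye and brain, 0.194 for forebrain and midbrain and 0.165 for left and right midbrain. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated one, and the number of members called is given beside the number that passed when adjusted over the list alone. Other versions were DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

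Genes were named by a rule: in each edgeR comparison, among genes past the threshold, with the same sign in both fish and a mean of at least 50 CPM in the higher group, the 10 with the largest fold in each direction. Where fewer than 3 passed, the 5 with the smallest p were given as values. From each list 2 to 4 members were given, those that passed first. For the tertiary fin the rule took the 10 genes with the largest ratio in each direction that had at least 100 transcripts in sum and the same sign in both parts. A gene that the rule named for the tertiary fin is not reported here. CPM of these genes use effective library sizes, and CPM of the tertiary fin use plain library sums. Folds against a group without transcripts are given as at least the fold over 3 transcripts in that group, and folds against 1 to 3 transcripts with a 95% counting interval. A number of genes is given as a percent of the genes tested with the filter on low counts where it is large, with the same denominator for every alternative.

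Clone measures were made per fish. Numbers of clones were compared after thinning each fish to 1255 cells, the mean of 200 random draws. Overlap was set beside cells shuffled between organs, which covers counting error only. Tests over fish were exact permutation tests, and the smallest p they can reach is 0.0952 for 2 against 5 fish, 0.2 for 2 against 3, 0.333 for 2 against 2 and 0.25 for 3 sign flips. Shares of cells have 95% exact binomial intervals, which cover counting error only. Values of 1 fish were not tested in the planned comparisons. Patterns flagged after the data were seen were weighed within 1 fish, in part with bootstrap intervals and shuffles over its cells.

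The comparisons, the tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The robust estimate of spread, the sums over all wells, the restriction to neurons, the list values of the tertiary fin against each single reference and the summary of edits were chosen after the data were seen. As a check of the fits, known folds were put into simulated counts of each comparison. Only genes past a minimum mean count were changed, and the spread followed the fitted trend, so recovery over all tested genes may be lower. Of genes with an 8-fold difference the fits recovered 68% for fin, 53.1% for eye and brain, 90% for forebrain and midbrain and 86% for left and right midbrain, and at 2-fold at most 20.8% in any comparison.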

Results

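ScarTrace reads, for each sorted zebrafish cell, its transcripts and the edits that Cas9 left in copies of GFP; edits made early in development are inherited, so cells that share them are called a clone. The data came from 7 fish and 56 libraries, 37 with GFP edits and 19 with transcripts. Fish R1 to R5 received Cas9 as mRNA, and fish P1 and P2 received it as protein and had edit libraries only. Transcripts were read in the whole kidney marrow (the blood-forming organ of adult fish) of R1, R2 and R4, in head organs of R1 and R3, and in the caudal fin of R4 and R5. The fin was taken as primary fin, as secondary fin that had regrown, and in R4 also as dorsal and ventral tertiary fin that had regrown again. Cells that the authors annotated held a median of 478 transcripts in the forebrain of R3, the shallowest library, and 3404 in the marrow of R4, the deepest. Library sums ran from 108833 transcripts in the right midbrain of R1 to 5094762 in the marrow of R4. No group with transcripts held more than 3 fish, so each comparison of transcripts rests on 2 or 3 fish. Comparisons of clones rest on up to 7 fish, and cells were never counted as replicates.

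The edits themselves were short and lay close together. Across the 7 fish, 80.8% of the distinct edits of GFP held only deletions, 12.99% only insertions and the rest both. The median loss was 10 bases, and the longest was 30 bases. The quartiles of the first altered position lay 13 bases apart. Of the distinct edits, 46 (25.99%) were seen in more than 1 fish and none in more than 6. A deletion of 18 bases was the most frequent edit of R1, with a mean of 14.03% of GFP per cell, and was seen in 6 fish. A deletion of 10 bases made up 81.5% of GFP in P2 and was also seen in 6 fish. The most frequent edit of R4 was a deletion of 14 bases, with 24.8% of GFP. The most frequent edit of R2, a deletion of 11 bases with 29.3% of GFP, was seen in no other fish. Edits also found in another fish carried 49.4% of the edited GFP in R2 and 93.3% in P2, the lowest and highest of the 7 fish. The same edit in different fish arose separately, so cells of 1 fish can share such an edit without shared descent. A clone number may thus join cells of separate origin, which was not tested and limits the clone overlaps below.

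The first comparison asked whether the form of Cas9 changed the number of clones and the amount of unedited GFP. The mRNA fish R1 held 98 clones among 3416 cells, R2 15 among 1738, R3 64 among 1767, R4 36 among 3688 and R5 23 among 2366. The protein fish P1 held 29 clones among 1255 cells and P2 8 among 1890. Thinned to 1255 cells per fish, the mean was 43.1 clones in the 5 mRNA fish and 18.4 in the 2 protein fish, a difference of 24.6 (exact permutation test, two-sided, p = 0.286). This difference was 14.2 without R1, 14.1 without P2 and 37.25 without P1, the last at 1738 cells per fish. The effective number of clones, the inverse of the chance that 2 cells share a clone, averaged 8.07 and 4.66 (exact permutation test, p = 0.381). P2 decided much of the lower value, because a single clone made up 74.6% of its cells and its effective number was 1.69 at 1255 cells. The difference in effective number was 3.42, and it was 1.78 without R1, 0.444 without P2 and 6.42 without P1. With head organs only, in R1, R3, P1 and P2, the mean was 66.3 clones in mRNA fish and 13.96 in protein fish at 582 cells, a difference of 52.4, and the effective numbers were 19.1 and 5.97 (exact permutation test of 2 against 2 fish, p = 0.333, the smallest possible).

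Unedited GFP averaged 39.4% per cell in the 5 mRNA fish and 11.7% in the 2 protein fish, a difference of 27.7 percentage points. The exact two-sided permutation test gave p = 0.0952, which is the smallest value that 2 fish against 5 can reach. R5 had the most unedited GFP, 76.9%, followed by R4 with 40.7%, R3 with 30.8%, R2 with 26.6% and R1 with 22.1%. P1 had 21.1% and P2 2.29%. Without R5 the difference was 18.4 points, and without P2 it was 18.3 points. With the median over cells in place of the mean the difference was 20.2 points (31.1% and 10.9%), with an exact p of 0.667. The organs sampled differed between the fish for this measure as well.

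**Figure D1:**
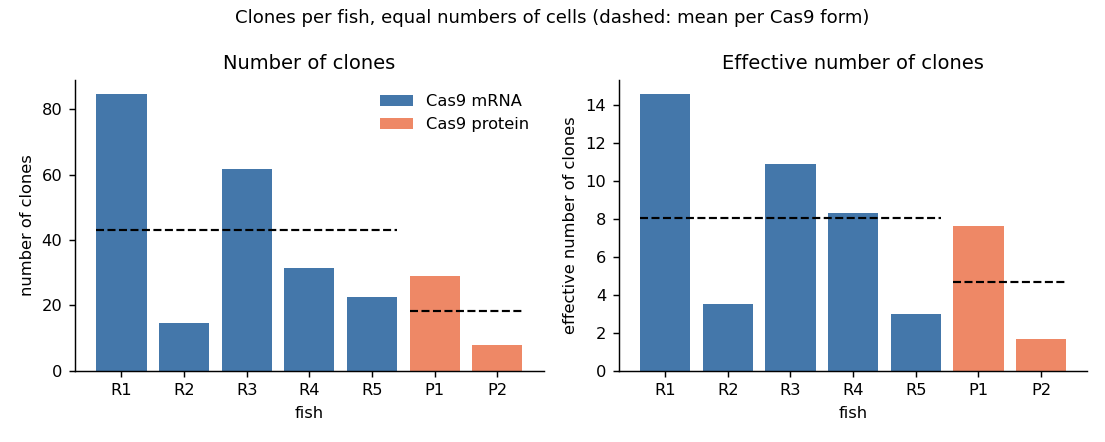
Number of clones and effective number of clones (bars, vertical axes) in each of the 7 fish (horizontal axis), with cells thinned to 1255 per fish; dashed lines are the means of the 5 Cas9 mRNA fish and the 2 Cas9 protein fish. The number of clones ran from 7.88 in P2 to 84.8 in R1, and the mRNA fish R2 lay below the protein fish P1 with 14.6 against 29 clones. R2 was sampled in 1 organ, the marrow, and P1 in 8 organs, so these counts do not compare like with like.

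The largest clones showed how each organ was filled. In R1 clone 73 made up 30.4% of marrow cells, clone 10 21.3% and clone 58 18.9%, whereas the forebrain of this fish held 40 clones. In R2 clone 2 made up 46.4% of the marrow, clone 12 17.8% and clone 11 16.2%. In R3 clone 27 made up 39.02% of left eye cells and 34.3% of right eye cells, where 53 of its 61 cells with a class were erythrocytes, and clone 42 made up 35.8% of the forebrain but 0% of the right eye, where 3 cells would be 1.47%. In R4 clone 13 made up 53.9% of the marrow and 10.5% of the primary fin. Clone 19 of R4 made up 9.19% of the primary fin, 19.6% of the secondary fin and 0% of the marrow, where 3 cells would be 0.480%. In R5 the clone with only unedited GFP held 58.2% of the primary and 54.6% of the secondary fin. In P1 clone 20 made up 60.5% of the marrow and 34.9% of the forebrain. In P2 clone 1 made up 97.1% of the marrow, 85.8% of the dorsal and 86.6% of the ventral primary fin, and clone 7 made up 88.1% of the right midbrain. The title of the dorsal fin library names P1, and it was assigned to P2 because its cells are in the clone table of P2.

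The next comparison asked how far left and right organs of 1 fish held the same clones. Overlap was the sum over clones of the smaller of both shares, from 0 for no shared clone to 1 for equal shares. Between the eyes it was 0.0421 in R1, 0.780 in R3, 0.269 in P1 and 0.733 in P2. Between the sides of the midbrain it was 0.158 in R1, 0.323 in R3, 0.646 in P1 and 0.472 in P2. The means over the 4 fish were 0.456 for the eyes and 0.400 for the midbrain, a difference of 0.0562 (exact sign-flip permutation test over fish, p = 0.875), and its sign turned without R3 (-0.0774) or without P2 (-0.0119). When cells of R1 were shuffled between the sides, the mean overlap was 0.746 for its eyes and 0.865 for its midbrain, far above the observed values. In R3 the eyes came closer to the shuffled mean of 0.864 than the midbrain came to its 0.902. Of the right eye cells of R3 with both a clone and a cell class, 81.5% were erythrocytes (95% exact interval 74.9 to 86.99), and clones 27, 28 and 59, the largest that both eyes of R3 shared, consisted of erythrocytes, immune cells or microglia in 60 of 61, 23 of 24 and 58 of 61 such right eye cells. The overlap of its eyes thus rested mainly on clones that were blood in the right eye.

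**Figure D2:**
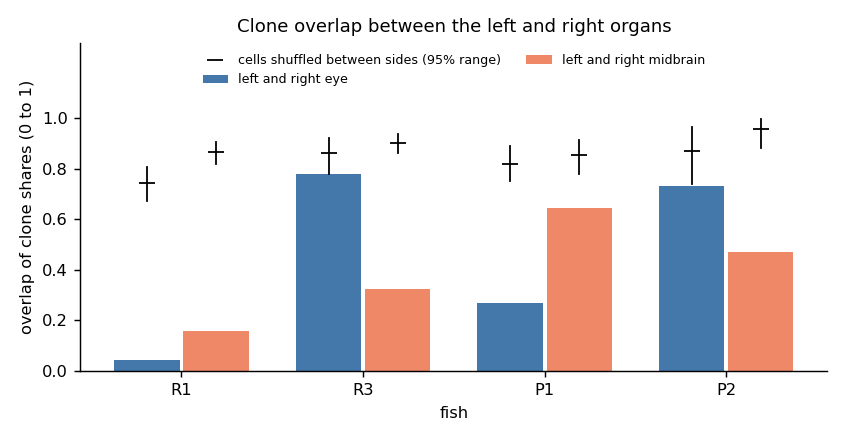
Overlap of clone shares (vertical axis, 0 to 1) between left and right eye and between left and right midbrain (bars) in fish R1, R3, P1 and P2 (horizontal axis); black marks give the mean and 95% range after cells were shuffled between the sides. R1 had the lowest observed overlaps, 0.0421 for eyes and 0.158 for midbrain, beside shuffled means of 0.746 and 0.865.

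The comparison of head and marrow asked whether blood-forming tissue held the clones of the head. Pairs of head organs had a mean overlap of 0.120 in R1, 0.311 in P1 and 0.675 in P2, and pairs of a head organ with marrow 0.133, 0.256 and 0.402. The mean difference over the 3 fish was 0.105 (exact sign-flip permutation test, p = 0.5, where 0.25 is the smallest possible), and it was 0.0208 without P2. The marrow and forebrain of P1 shared most, with an overlap of 0.702. In R1 the 4 largest marrow clones held 81.3% of the marrow but 14 of 668 head neurons (2.096%, 95% exact interval 1.15 to 3.49), and none of the bipolar and horizontal cells (up to 3.24%) or of the 70 rods (up to 5.13%). The same 4 clones held 37 of 68 cells annotated as immune (54.4%, 41.9 to 66.5) and 7 of 13 microglia, the resident macrophages of the brain (53.8%, 25.1 to 80.8).

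Within the fin, clones were tied to cell classes. Of the R4 clones with at least 15 fin cells, clones 13 and 12 consisted of immune cells to 95.5% and 95.96%, and clones 10, 18 and 33 of cells annotated as osteoblasts, a class led by the collagen genes col10a1a, col1a1a and col1a2, to 84.9%, 84.5% and 93.5%. Clone 19 of R4 held 45% epidermis, 42% cells annotated as fibroblasts, 11.5% immune cells and 0.5% osteoblasts. In R5 clones 16 and 17 were immune to 85.2% and 81.8%, and clones 12 and 18 were osteoblasts to 95.1% and 96.7%. The bias-corrected Cramér V of clone against class, which is 0 without association and 1 for a complete one, was 0.530 in the fin of R4 (1638 cells, 32 clones) and 0.354 in that of R5 (1083 cells, 23 clones). In marrow it was 0 in R1, 0.0513 in R2 and 0.0207 in R4. The difference between fin and marrow means was 0.418 (exact permutation test, p = 0.2, the smallest that 2 against 3 values allow). R4 gave a value to both groups, which the test treated as independent, so this p does not compare separate fish. With cell classes shuffled over cells, the 95% range of V ended at 0.117 and 0.184 in the fins of R4 and R5. In the head it was 0.301 in R1 and 0.387 in R3, where classes and organs are nested. In the forebrain alone it was 0.326 in R1 and 0.320 in R3, and the 95% ranges with shuffled classes ended at 0.212 and 0.219.

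**Figure D3:**
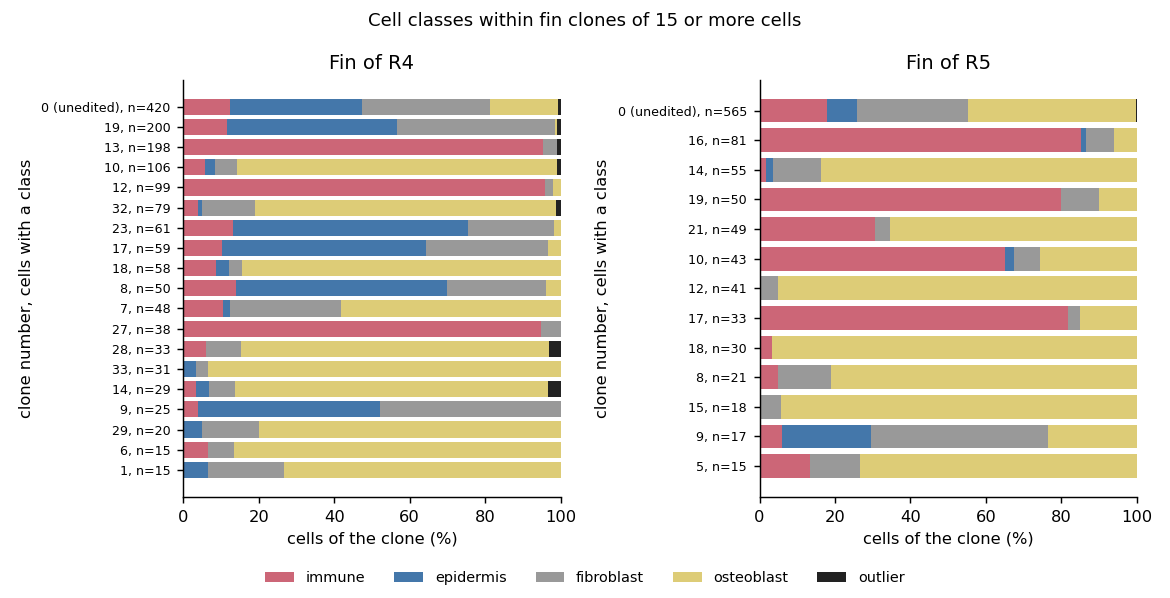
Share of cell classes (stacked bars, percent of the cells of a clone, horizontal axis) in each fin clone with at least 15 cells (vertical axis) of R4 and R5. In R4 clones 13 and 12 are over 95% immune, clone 10 is 84.9% osteoblast and clone 19 is split between epidermis (45%) and fibroblast (42%).

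R4 was the only fish with transcripts of both fin and marrow, and its fin immune cells were mostly in marrow clones. P1 and P2 had edit libraries of both organs but no cell classes. Of 471 fin immune cells, 405 belonged to a clone also found in marrow (85.99%, 95% exact interval 82.5 to 88.99), against 42.03% of epidermal cells (36.9 to 47.3), 50% of fibroblasts (44.6 to 55.4) and 34.8% of osteoblasts (30.3 to 39.4). Most of the epidermal share came from cells with only unedited GFP, which carry no clone information. With these left out, the shares were 84.2% of immune cells (80.4 to 87.6), 2.76% of epidermal cells (1.02 to 5.92), 15.2% of fibroblasts (10.6 to 20.9) and 21.4% of osteoblasts (17.3 to 25.9). By fin the immune share was 81.98% in the primary, 85.1% in the secondary, 92.5% in the dorsal tertiary and 89.7% in the ventral tertiary fin. These are values of 1 fish and have no replicate check.

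**Figure D4:**
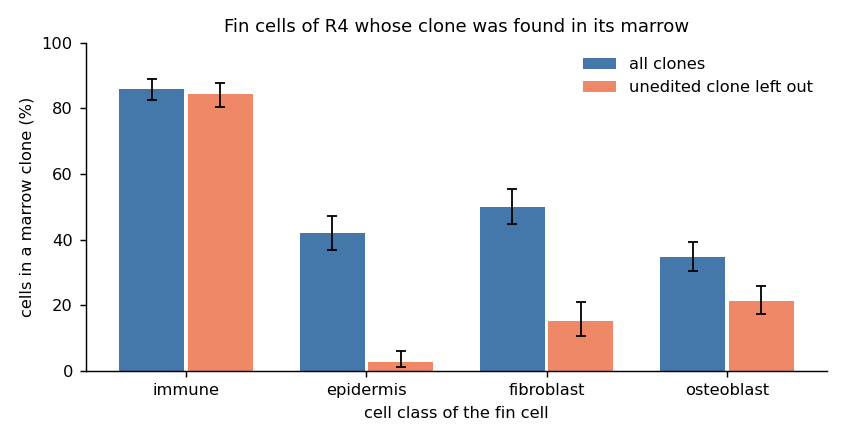
Percent of R4 fin cells of each class (horizontal axis) whose clone was also found in the marrow of this fish (vertical axis), with all clones and with the unedited clone left out; error bars are 95% exact binomial intervals of counting error. Immune cells stand at 85.99% and 84.2%, and epidermis at 42.03% and, with unedited cells left out, 2.76%.

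Clone shares of the fin before and after regrowth were then compared. Between primary and secondary fin the overlap was 0.792 in R4 (95% bootstrap range over cells 0.738 to 0.816) and 0.903 in R5 (0.860 to 0.916). Shuffling cells between both fins gave mean overlaps of 0.924 in R4 and 0.947 in R5. Each fin was a single library per fish, so these values cover counting error only, and the spread between repeated samplings of the same fin was not measured. Without the unedited clone the overlaps were 0.744 and 0.813. In R4 the primary fin overlapped the dorsal tertiary fin by 0.709 and the ventral by 0.584, and both tertiary parts overlapped each other by 0.423. Clone 10 of R4, mainly of cells annotated as osteoblasts, made up 4.70% of the primary, 5.71% of the secondary and 11.4% of the ventral tertiary fin, but 0% of the dorsal tertiary fin, where 3 cells would be 0.595%.

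Cell classes of the fin were compared between primary and secondary fin of R4 and R5. Immune cells made up 31.7% and 33.8% of the primary fins and 23.97% and 21.1% of the secondary fins, with differences of -7.78 and -12.7 percentage points within R4 and R5 and a mean of -10.2 (exact permutation test, p = 0.333, the smallest that 2 against 2 allow). Osteoblasts made up 19.4% and 30.4% of primary and 23.97% and 49.8% of secondary fins, with differences of 4.53 and 19.4 points within R4 and R5 and a mean of 11.98 (exact p = 0.667). These tests did not pair the fins of a fish, so differences between fish enter their p. Epidermis was 21.6% and 4.76% in primary and 15.7% and 5.38% in secondary fins. Fibroblasts were 26.5% and 30.6% in primary and 35.96% and 23.5% in secondary fins, with opposite signs in R4 and R5. The fish differed more than the fins for epidermis. The class annotated as fibroblast had low collagen: its col1a1a level was 269.3 and 396 CPM in R4 and R5, against 15581 and 21572 CPM in the class annotated as osteoblast.

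In whole fins, interferon-inducible genes were among those called lower in secondary than in primary fin, which rested on the primary fin of R4 and was lost with the fish as a replicate block. ifi27.2 (ENSDARG00000039243), an interferon-inducible gene, stood at 851 and 4.28 CPM in the primary fins of R4 and R5 and at 11.8 and 0.900 CPM in the secondary fins, and fell by 6.05 ± 0.94 (SE) on the log2 scale (edgeR quasi-likelihood test, 2 against 2 fish, adjusted p = 1.96e-06). ifi44a1, of the same response, fell by 4.78 ± 0.82 (edgeR adjusted p = 1.77e-05), from 326.3 and 10.7 CPM to 8.13 and 4.05. The chemokine gene ccl19a.1 fell by 4.40, the amino acid oxidase gene IL4I1 by 4.28, ifi27.6 by 4.22, si:dkeyp-1h4.6 by 5.15, ENSDARG00000088918 by 5.14, igldcp by 4.29 and the condensin gene ncapd3 by 4.08. ptgesl fell by 4.00 with its high value in R5, 367.4 CPM against 27.4 in the primary fin of R4. In all, 11 genes rose and 49 fell of 16382 tested by edgeR. In this whole-fin fit the prior degrees of freedom were infinite, so each gene took the common trend of spread in place of its own. The SE and p of this fit, here and in the paragraphs on whole fins below, thus do not reflect a gene's own spread between fish. That spread was wide for ifi27.2 in the primary fins. ifi27 and ifi44 genes are families of near-identical copies, so the level of a single copy is uncertain.

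Of the genes that rose, mt2 (ENSDARG00000041623), which encodes a metal-binding metallothionein, rose by 4.14 ± 0.82 (edgeR adjusted p = 0.000406), mainly in R4, with 13.1 and 12.1 CPM in primary and 430 and 15.8 CPM in secondary fins. ecrg4a, which encodes a secreted peptide, rose by 3.26 ± 0.81 (adjusted p = 0.0204) from 19.8 and 54.2 to 101.6 and 601 CPM. ENSDARG00000095866 rose by 3.88, si:dkey-32e6.6 by 3.37 and the channel gene panx3 by 2.55. Each of the 60 calls was lost when the fish was taken into account as a replicate block, which called 0 genes in edgeR with 2.47% at an unadjusted p under 0.05, and ifi27.2 then had an adjusted p of 0.276. Without the primary fin of R4, ifi27.2 stood at 0.50 and si:dkeyp-1h4.6 at 0.29 on the log2 scale. DESeq2 called 13 genes, of which 5 were among the 60 calls of edgeR. No gene passed with cells thinned to 500 transcripts (2.12% at an unadjusted p under 0.05), with the tertiary fin in the fit (4.77%) or with all wells (4.61%).

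Gene lists fixed before the data were examined were tested as well. Of 7 interferon genes 3 fell, and 5 were lower when adjusted over the list alone: isg15 fell by 3.602 (931 and 54.2 to 27.6 and 53.6 CPM), stat1b, a signal transducer of the interferon response, fell by 2.81, and the antiviral gene rsad2, which fell by 3.18 (camera adjusted p = 3.91e-08, and adjusted p = 0.669 with an estimated correlation). Of 11 matrix genes 0 were called and 8 were higher when adjusted over the list alone (camera adjusted p = 1.35e-13, and adjusted p = 0.669 with an estimated correlation). Among them the type I collagen gene col1a1a had 1087 and 4309 CPM in primary and 5912 and 18334 CPM in secondary fins (edgeR adjusted p = 0.605). Likewise 0 genes were called and 5 of 7 osteoblast, 6 of 10 mesenchyme and 8 of 12 fin regeneration genes were higher when adjusted over the list alone. In these lists the hypertrophic cartilage and bone collagen gene col10a1a was at 274.9 and 945 against 1411 and 9184 CPM (edgeR adjusted p = 0.094), and entpd5a had a log2 difference of 2.66 (adjusted p = 0.0954). Further lists passed camera with 0 genes called: erythroid genes, with 2 of 8 higher when adjusted over the list alone, inflammation, macrophage and oligodendrocyte genes, with 1 lower each, and hedgehog and BMP, proximodistal patterning, cell cycle and T cell genes, with 0. Each of the lists in this paragraph that passed camera had an adjusted p = 0.669 with an estimated correlation. agr1, in the superficial epidermis list, fell by 3.88 (347.4 and 15.7 to 19.1 and 5.40 CPM). Of 43 lists tested 13 passed with the preset correlation and 0 with an estimated one.

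**Figure D5:**
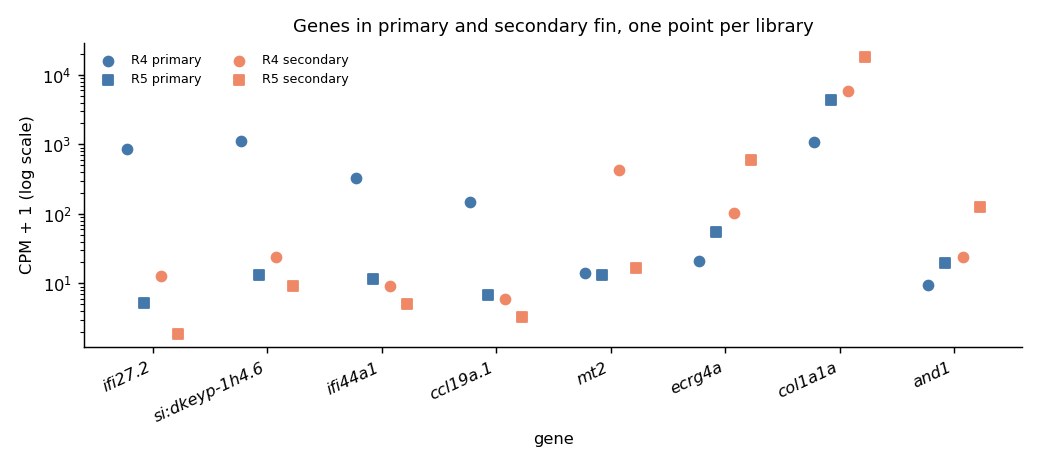
CPM plus 1 (log axis, vertical) of ifi27.2, si:dkeyp-1h4.6, ifi44a1, ccl19a.1, mt2, ecrg4a, col1a1a and and1 in the primary and secondary fin libraries of R4 and R5 (1 point per library). The interferon genes were high in the primary fin of R4 alone (ifi27.2 at 851 CPM against 4.28 in R5), whereas ecrg4a was higher in the secondary fin of both fish.

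Within the osteoblast class, plekhs1.3 fell by 5.60 ± 0.68 on the log2 scale (edgeR, adjusted p = 0.0411, 2 against 2 fish), from 80.4 and 110 CPM to 0 and 2.43, and it passed in each of the 9 alternatives run. It was the only call among 5355 genes by edgeR, with 9.17% at an unadjusted p under 0.05, while DESeq2 called 49 genes and edgeR with the replicate block 32. The complement genes C4A and c4 had log2 differences of -4.32 and -4.61 (edgeR adjusted p = 0.0504 and 0.0507), and the prostaglandin D synthase gene ptgdsb was at 4072 and 3896 against 868 and 991 CPM (adjusted p = 0.058). si:dkey-32e6.6 (log2 difference 3.30), ecrg4a (2.2004) and the actinodin gene and1 of fin ray fibres (2.55) were higher in both secondary fins and did not pass (adjusted p = 0.058, 0.121 and 0.161). All 6 of these genes passed with the block in edgeR (adjusted p = 0.00221, 0.0104, 0.0311, 0.00963, 0.0176 and 0.0368). Of 11 matrix genes 0 were called and 8 were higher when adjusted over the list alone (camera adjusted p = 3.84e-07, and adjusted p = 0.372 with an estimated correlation). Of 10 immediate early genes 0 were called and 4 were lower when adjusted over the list alone (adjusted p = 0.372 with an estimated correlation), such as the AP-1 gene fosb with 8971 and 8226 against 3667 and 4968 CPM. Leaving out 1 library at a time called 1.33% to 4.41% of the genes.

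Within the fibroblast class the haemoglobin gene ba1 rose by 4.36 ± 0.55 (edgeR adjusted p = 0.0496), from 135.2 and 45.8 to 1034 and 2748 CPM, as did si:ch211-5k11.8, by 4.46. The titin gene ttnb, which codes for a muscle protein, fell by 1.78 ± 0.25 from 1313 and 1499 to 423 and 393 CPM. These were the only 3 calls among 8471 genes (6.17% at an unadjusted p under 0.05). RLE size factors called 0, DESeq2 12 and the block 80. Haemoglobin is made by red blood cells, and its genes are near-identical copies, so which copy was higher is uncertain. Of 5 erythroid genes 1 was called and 4 were higher when adjusted over the list alone (camera adjusted p = 5.03e-12, and adjusted p = 0.401 with an estimated correlation). col1a1a had a log2 difference of 2.60 (60.99 and 134.4 to 368.8 and 820.7 CPM, edgeR adjusted p = 0.118, and 2.67e-10 with the block). Of 11 matrix genes 6 were higher and 2 lower when adjusted over the list alone. Leaving out 1 library at a time called 0.519% to 2.81% of the genes.

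Within immune and epidermal cells edgeR called 0 genes, of 4585 (3.79% at an unadjusted p under 0.05) and 4293 (5.38%). In immune cells DESeq2 called 1 gene and the block 56. There rgs5a was at 936 and 479 CPM in primary and 128.1 and 98.9 CPM in secondary fins, and the lubricin gene prg4b at 342.9 and 1504 against 0 and 18.3, each with an adjusted p of 1 and past the threshold with the block (2.87e-06 and 3.07e-24). In epidermis DESeq2 called 15 genes and the block 5, and the keratin genes krt15 (1192 and 865 to 6152 and 6760 CPM, adjusted p = 0.267, 0.0241 with the block) and krtt1c19e (47.7 and 101.1 to 1146 and 853 CPM) were higher in both fish. The interferon regulatory gene irf7 was at 626 and 78.6 against 20.2 and 19.1 CPM (edgeR adjusted p = 0.611). Of 5 interferon genes in epidermis 0 were called and 3 were lower when adjusted over the list alone (camera adjusted p = 0.00058, and adjusted p = 0.655 with an estimated correlation). Leaving out 1 library at a time called 1.13% to 2.22% of the genes in immune cells and 0.0233% to 11.2% in epidermis.

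The tertiary fin of R4 had no replicate, so ratios describe these libraries only. jac7 was at 97.49 CPM in the dorsal and 194.4 CPM in the ventral tertiary fin against 5.33 in the primary and 3.31 in the secondary fin, a mean log2 ratio of 4.96. The collagenase gene mmp13a was at 283.9 and 240.9 CPM against 28.2 and 36.9 (3.01), the leptin gene lepb at 81.3 and 107.5 against 4.95 and 51.03 (2.53), and the Wnt-binding gene frzb at 65.2 and 89.7 against 14.5 and 11.8 (2.53). wu:fk65c09, ENSDARG00000095866, krt94 and klf17 had mean log2 ratios of 2.14 to 3.76. Lower were ba1, at 0.476 and 36.3 CPM against 136.7 in the primary and 324.6 in the secondary fin, si:ch211-5k11.8, at 0.476 and 4.11 CPM against 49.1 and 43.9, and the interferon gene ifi27.2, at 4.28 and 4.11 CPM against 768 and 13.7, with a mean log2 ratio of -4.53. Of 26 lists 5 lay above 99% and 1 below 1% of 10000 random lists matched on expression. Fin regeneration genes had a median log2 ratio of 0.69, above 99.99% of them, heat shock genes 1.07 (99.97%), neutrophil genes 0.60 (99.86%), thrombocyte genes 0.91 (99.57%), retinoic acid genes 0.76 (99.53%) and interferon genes -1.88 (0.01%). The thrombocyte and retinoic acid lists had 3 measured genes each, 2 higher and 1 lower, and retinoic acid genes had medians of 0.25 in dorsal and 1.16 in ventral fin. The neutrophil and fin regeneration lists share mmp13a. Random lists drew genes independently, so their percentiles do not cover correlation between members. The interferon value came from the primary fin as reference, with -2.51 against the primary and -0.09 against the secondary fin (33.3%). Neutrophil genes had 0.13 and 1.48 against these references, heat shock genes 0.87 and 1.59 and fin regeneration genes 1.02 and 0.37. Against the primary and the secondary fin, matrix genes had 1.16 (100%) and -0.87 (0.17%) and mesenchyme genes 1.05 (99.99%) and -0.77 (0.75%). Cell cycle genes had -1.60 (0%) and 0.67 (100%), so which lists pass these limits depends on the reference.

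The comparison of eye with brain tested the labels on organs of known content. The eye of R3 was the right eye alone, and the brain of R1 held the hindbrain while that of R3 did not. Genes of rods, the photoreceptors of dim light, were higher in the eyes of R1 and R3. Rhodopsin, rho (ENSDARG00000002193), had 31013 and 66044 CPM in the eyes of R1 and R3 against 1.32 and 0 in the brains, a ratio of 44840 (95% counting interval 12412 to 370272; edgeR adjusted p = 0.0388). The phosducin gene pdca was at least 793-fold higher, cabp2a at least 710-fold, the photoreceptor transcription factor gene crx at least 255.6-fold and guca1b at least 199.1-fold. Myelin genes were higher in the brain: plp1b was at least 1185-fold higher, mpz had 7270 and 2707 CPM in the brains against 0 and 4.31 in the eyes (ratio 6204, 1113 to 245060), and cldnk had a ratio of 1049 (188.1 to 41452). The complement inhibitor genes cd59a and cd59b were at least 1558-fold and 101.1-fold higher in the brain. In all, 1.76% of 10028 genes tested by edgeR were called higher in the eye and 1.097% higher in the brain, and with the replicate block 4.55% and 4.25%, each of the first calls among them.

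By list, 7 of 7 rod genes were called higher in the eye, such as gnat1 with 4683 and 2295 CPM against 1.32 and 5.81 (camera adjusted p = 5.43e-18, and adjusted p = 0.264 with an estimated correlation). Of 4 bipolar cell genes 1 was called, vsx1 with a ratio of 479 (85.1 to 19013), and 3 when adjusted over the list alone. Of 4 superficial epidermis genes 4 were called, such as the keratin gene krt4 with 282.7 and 249.7 CPM against 0.659 and 0.968 (adjusted p = 0.264 with an estimated correlation), and krt5 of the basal epidermis list had a ratio of 261.9 (71.7 to 2175). The brain was higher in 3 of 6 oligodendrocyte genes, 6 when adjusted over the list alone, in 2 of 6 forebrain genes, 4 when adjusted over the list alone, with neurod6b at least 42.2-fold higher, and in 2 of 5 radial glia genes, with s100b at least 39.5-fold higher (adjusted p = 0.32 with an estimated correlation for all 3 lists). Of 28 lists 13 passed with the preset correlation and 0 with an estimated one. Of 8 erythroid genes 0 were called, and ba1 had a log2 difference of 5.18 (edgeR adjusted p = 0.362). Erythrocytes made up 65.8% of the right eye cells of R3 (95% exact interval 60.4 to 70.8) and 1.74% and 0.400% of those of the eyes of R1, and without the eye of R3 13.3% of the genes passed, against 2.85% with all 4 libraries, and 97.6% of the first calls were kept. Without the eye of R1 14.2% of the genes passed (67.5% of the first calls kept), without the brain of R3 4.84% (76.9%) and without that of R1 1.78% (41.96%).

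The forebrain and midbrain differed in region-specific transcription factors. foxg1a (ENSDARG00000070769), a marker of the telencephalon, was at 264.6 and 689 CPM in the forebrains of R1 and R3 and at 0 and 1.46 in the midbrains, a ratio of 400 (71.3 to 15852; edgeR adjusted p = 0.00496). tbr1b had a ratio of 137.7 (37.7 to 1144), the opioid peptide gene penka 108.7 (19.004 to 4341), the tachykinin gene tac1 54.3 (9.26 to 2194), six3b 30.3 (7.94 to 256.9) and dlx5a 28.4 (7.43 to 241.6), and nppal was at least 98.8-fold higher. rtn4rl2b rose by 7.60 ± 0.87 from midbrain to forebrain and bhlhe22 by 5.25 ± 0.64. In the midbrain pou4f2 was at least 57.8-fold higher, with 253.5 and 142.8 CPM against 0 and 0. tal1 was at least 46.2-fold, crabp1a at least 32.7-fold, tfap2b at least 20.8-fold, pax7b at least 16.5-fold and eng2b at least 15.1-fold higher, and gata3 had a ratio of 150.6 (26.7 to 5980) and tcf7l2 of 127.9 (35.1 to 1061). In all, 36 genes were higher in the forebrain and 79 in the midbrain of 7685 tested, 1.496% of the tested genes together, and 4.01% passed with the replicate block, each of the first calls among them.

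Of 8 forebrain genes 7 were called higher in the forebrain (camera adjusted p = 2.21e-22, and adjusted p = 0.202 with an estimated correlation). Of 6 midbrain genes 4 were called higher in the midbrain, 6 when adjusted over the list alone (camera adjusted p = 9.88e-19, and adjusted p = 0.204 with an estimated correlation). Of 6 oligodendrocyte genes 2 were called higher in the midbrain, 4 when adjusted over the list alone, with plp1b at 3506 and 2297 CPM against 83.1 and 18.1 (adjusted p = 0.204 with an estimated correlation). Neurons made up 84.01% and 64.5% of the forebrain cells of R1 and R3, and with neurons only 190 genes passed, 77 of them among the first calls. The immediate early gene fosl1a was higher in the forebrain, with 247.7 and 544.3 against 69.9 and 61.2 CPM, the only one of 10 on its list that was called. Leaving out 1 library at a time called 3.18% (midbrain of R3), 3.19% (midbrain of R1), 5.31% (forebrain of R1) and 7.13% (forebrain of R3) of the genes.

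Left and right midbrain did not differ in any gene that passed. edgeR called 0 of 5493 genes, with 2.44% at an unadjusted p under 0.05. DESeq2 called 0 of 19398 genes, with 72 at an unadjusted p under 0.05. On simulated counts of this comparison 86% of genes with 8-fold and 38.8% with 4-fold differences were recovered, so most differences under 4-fold would be missed at this depth. These rates hold for the better-counted genes, the only ones changed in the simulation. Of the genes that led the ranking of edgeR, id1, an inhibitor of DNA binding in BMP signalling, was at 221.03 and 183.1 CPM in the right and 45.7 and 43.8 in the left midbrain, and the cathepsin gene ctss2.1 at 132.6 and 125.05 against 27.4 and 10.9. gpsm1b was at 134.2 and 125.9 CPM in the left against 53.05 and 49.1 in the right midbrain (edgeR adjusted p = 0.999 for each). The macrophage and hedgehog and BMP lists, with 1 gene each lower in the left when adjusted over the list alone, had camera adjusted p = 0.00156 and 0.00408, and adjusted p = 0.61 with an estimated correlation. With the replicate block 1 gene passed, ENSDARG00000078665 (36.6 and 1100 CPM in the left against 0 and 8.93 in the right). Without the left midbrain of R1 60 genes passed, and without a filter on low counts 64.

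Marrow cells were compared between 3 fish by their classes. Neutrophils made up 31.3% of the marrow of R1 (95% exact interval 28.9 to 33.8), 27.5% of R2 and 23.4% of R4. Monocytes made up 13.2%, 12.6% and 33.9% (31.3 to 36.6 in R4). Lymphocytes made up 21.6%, 8.07% and 15.3%, and haematopoietic stem and progenitor cells 21.4%, 12.2% and 11.1%. Erythrocytes ranged from 3.72% in R1 over 13.5% in R4 to 33.02% (30.8 to 35.3) in R2. No test was made, because the fish form 1 group. The marrow of R4 was annotated apart from that of R1 and R2. Its cells held a median of 3404 transcripts and 81.4% of its wells were kept. In R1 these values were 1125 and 36.4%, and in R2 1630 and 51.6%. Gaps between R4 and the other fish, such as that in monocytes, cannot be told apart from these differences. The lymphocyte share of R1 was 11.2% among cells with at least 1000 transcripts.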

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

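The head annotations were examined outside the planned comparisons, and the tests of the 3 patterns below were chosen after the patterns had been seen. A signal in an annotation that no comparison used stood out. In the older annotation of the head, 3.66% of the cells were called thrombocytes, 65 in R1 and 37 in R3. The newer annotation named 86 of these cells glia-like, 2 neurons and 14 unknown, and none thrombocytes. No biological explanation was tested.

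Fin immune cells of R4 outside marrow clones, 66 of 471, were weighed first. The share of transcripts from epidermal, mesenchyme, osteoblast and matrix lists was 3.67 times that of immune cells in marrow clones (95% bootstrap interval 2.54 to 5.25), which doublets of an immune cell with such a cell could give. Of 5 lists of immune classes 3 differed, natural-killer-like genes at 0.198 times (99% interval 0 to 0.651), T cell genes at 0.320 times and neutrophil genes at 0.388 times, which another kind of immune cell could give, while macrophage genes at 1.15 times (0.599 to 2.001) and B cell genes at 0.229 times (0 to 1.97) had intervals that include 1. A partner with the mean profile of epidermis was argued against for the 59 raised genes, because the most abundant epidermal genes needed 0.146 times the epidermal share that those genes needed (0.0691 to 0.201; test written after the result; 0.123, 0.0234 to 0.265, with genes chosen in some of the cells and measured in the others), though simulated mixtures with 20% epidermal transcripts ranged from 0 to 0.973, so at such a share this ratio does not decide alone, and they raised at most 26 genes. Of the 59 raised genes 36 stood above every other fin class and the inside cells, but genes chosen as high favour this. Chosen in some cells and measured in the others, 45.5% (17.8 to 69.4) did. Mixtures gave 16.7% (0 to 50), 4.44% (0 to 13.3) and 24.4% (12.3 to 38.8) with 20%, 50% and 80% epidermal transcripts, so this share does not decide either. Clone 19 held 23 of the 66 cells. Another kind of immune cell and doublets, with a partner of another profile for the raised genes, could each be part of this group, which the tests in 1 fish did not separate.

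Weighed second were 41 of the 49 genes that fell, those over 2 times higher in R4 than in R5 primary fin, which include interferon genes and others. Cells of 1 sorted plate were not the source, because no plate held more than 1.38 times its share of all transcripts, and 1.36 times for the interferon list fixed beforehand. A different make-up of classes was not the source for these 41 genes either, because each class was higher in R4 than in R5, by 5.78 times in epidermis up to 22.9 times in osteoblasts, and by 2.55 to 4.49 times for the interferon list (tests written after the result). With all 49 genes fibroblasts were at 0.549 times, so the gap does not hold for each gene that fell. Both primary fins were taken before regrowth, so regrowth does not give this gap between R4 and R5, and its cause was left open.

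Midbrain clones held by 1 side in R3 were weighed last. Of 8 clones with at least 20 midbrain cells 4 lay on a single side, among them clone 16 with 96 right and 0 left cells. No plate held more than 1.34 times its share of such a clone, so a single plate was not the source. Shuffling cells between the sides gave at most 0 such clones in 1000 shuffles, so sampling was not the source. In R1 7 of 11 clones, in P1 0 of 3 and in P2 0 of 2 lay on a single side, and descent from cells confined to a side was not tested otherwise.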

How the results depend on the processing

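Alternatives in this part were fixed beforehand except the robust spread, all wells and neurons only, which were chosen after the results had been seen. Of the values for named genes and gene lists, 67.5% kept direction and side of the threshold, 14.7% were weaker, 17.6% stronger and 2 values reversed. Of the values for comparisons, 97 were kept, 70 moved and 3 reversed. The exact tests over fish cannot go below p = 0.0952 in any setting, so for them only the direction was compared. Percentages of genes use the genes tested with the filter on low counts. The cause was not tested for any result that moved, unless fewer libraries or more genes tested show it. Thinning cells to 500 transcripts, run for the fin only, left 0 calls.

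With the fish as a replicate block, which pairs both groups within a fish, the calls were 0% for fin (0.366% without), 8.795% for eye and brain (2.85%), 4.01% for forebrain and midbrain (1.496%), 0.0182% for left and right midbrain (0%), 0.598% for osteoblasts (0.0187%), 0.944% for fibroblasts (0.0354%), 1.22% for immune cells (0%) and 0.116% for epidermis (0%). With DESeq2 they were 0.0794% for fin, 6.16% for eye and brain, 0.915% for osteoblasts, 0.142% for fibroblasts, 0.0218% for immune cells and 0.349% for epidermis. Without a filter on low counts they were 14.9% for eye and brain, 5.53% for forebrain and midbrain, 1.17% for left and right midbrain, 2.26% for osteoblasts, 1.26% for fibroblasts, 1.94% for immune cells and 0.559% for epidermis. RLE size factors gave 0.0560% for osteoblasts and 0% for fibroblasts, and the robust spread 0.0747% and 0.0708%. For fin, thinned cells, the tertiary fin in the fit and all wells each gave 0%. Neurons only gave 2.47% for forebrain and midbrain.

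Leaving out 1 library at a time gave 0.0794% to 0.629% for fin, 1.78% to 14.2% for eye and brain, 3.18% to 7.13% for forebrain and midbrain, 0% to 1.092% for left and right midbrain, 1.33% to 4.41% for osteoblasts, 0.519% to 2.81% for fibroblasts, 1.13% to 2.22% for immune cells and 0.0233% to 11.2% for epidermis. Across these fits the log2 difference of ifi27.2 ran from -8.80 to 0.50 and that of si:dkeyp-1h4.6 from -6.18 to 0.29, with the sign turned without the primary fin of R4 in both. The difference in overlap between eyes and midbrain ran from -0.0774 without R3 to 0.201 without P1. The overlap of primary and secondary fin without the unedited clone was 0.744 in R4 and 0.813 in R5, and as cosine similarity 0.918 and 0.996. With only cells of at least 1000 transcripts the fibroblast difference in fin was -1.54 points (1.17 with all cells). In marrow these cells gave 23.995% stem and progenitor cells, 11.2% lymphocytes and 38.8% neutrophils in R1, 6.41% lymphocytes, 32.4% neutrophils and 28.4% erythrocytes in R2, and 12.95% lymphocytes, 36.6% monocytes and 11.4% erythrocytes in R4.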

Other observations

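The values in this part were chosen after the data had been seen and were not tested. The class annotated as fibroblast in the fin was led by ttnb, erbb2ip, GLDC and cdk15, with ttnb at 550 and 790 CPM and GLDC at 4182 and 4072 CPM in R4 and R5. Genes of the mesenchyme list together made up 1267 and 1303 CPM in that class and 48590 and 63730 CPM in the class annotated as osteoblast. The haemoglobin gene ba1 was at 437 and 1160 CPM in fibroblasts, 249.3 and 1425 CPM in immune cells, 2.34 and 49.4 CPM in osteoblasts and 0.581 and 10.99 CPM in epidermis.

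Edited GFP whose net change in length was a multiple of 3 bases made up 77.8% of the edited GFP of R5, 54.7% of R1, 35.5% of R2, 33.7% of R3, 23.1% of R4, 19.9% of P1 and 10.6% of P2. Spike-in transcripts made up 56.5% of the transcripts of the secondary fin of R5 and 4.64% of those of the secondary fin of R4.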
